A study of Mus musculus with 12 samples.

How the data were processed

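Total RNA of thymus from FVB/N mice was measured on 12 single-channel whole-transcript arrays: 3 of normal thymocytes, 5 of control tumors and 4 of Dnmt3a-deficient tumors. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, purified again on a column, amplified and labelled with biotin. The values used are log2 expression per probe set as deposited by the authors, made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, normalizes quantiles between arrays and summarises the probes of a set. Versions of both and the probe set definitions are not given in the sources used here. Quantile normalization usually leaves arrays with near equal quartiles, while those of the deposited values differed. The 75th percentile was 8.50 to 8.60 in deficient tumors and control tumors 1 and 2 and 8.13 to 8.30 in the other arrays. Whether arrays were normalized in groups, or whether the table holds only part of the probe sets, is not given in the sources used here. Normalization in groups would bear on every group difference. The values were used without further normalization, and other scalings were run as alternatives. All values of a gene are relative to the total signal of its array, so a change in total RNA per cell is not seen.

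The table held 23858 probe sets, of which 20870 had 1 gene symbol in the platform annotation, 1453 several and 1535 none. Probe sets with several symbols or none were left out of the named results. The gene identifiers of 20822 of the 20870 were found in a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. For the 849 genes with more than 1 probe set, the set with the highest mean over all 12 arrays was kept, which left 19309 genes. No filter on dim genes was applied. Array signals have a floor (the lowest values were 2.4 to 2.72), and differences of genes near it are compressed. No column of per-sample values was left unused.

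Genes were tested with limma 3.58.1 in R 4.3.3. One model with 3 group means was fitted to all 12 arrays (9 residual degrees of freedom, prior 4.17 degrees of freedom from eBayes), and 3 contrasts were drawn from it: control tumor against normal thymocytes, Dnmt3a-deficient tumor against normal thymocytes, and Dnmt3a-deficient tumor against control tumor. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, and a gene was called at an adjusted p under 0.05. A second count required a change of at least 2-fold. Every adjusted p of a gene is limma's unless another test is named. Differences are log2 values of the first group minus the second, with standard errors from limma.

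A set of 20 gene lists and 9 marker lists of other cell types was fixed beforehand. Some genes belong to several lists, such as Notch1 (early thymocyte and Notch) and Tap1 (interferon and MHC), so lists are not independent. Of 706 entries, 639 matched a tested gene, and the others, such as Cdkn1a, Isg15, Lck and Tcf7, were not analysed here. Lists were tested with limma's camera at its preset correlation of 0.01, which compares a list with all other genes, adjusted over the lists of the contrast. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Members were counted over all genes and adjusted over the list alone. The array means of a list were compared between the tumor groups by an exact two-sided permutation test over all 126 splits, whose smallest p is 0.00794.

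The groups, tests, lists, main alternatives and the rule for named genes were fixed before the data were examined. The rule takes every DNA methylation gene, the 10 largest increases and the 10 largest decreases among called genes whose groups do not overlap (leaving out unnamed models, olfactory, vomeronasal and microRNA genes and antigen receptor segments), up to 4 called members of each list with the largest difference (or the smallest p where none was called), and Myc, Mycn, Cd3e, Cd4 and Cd8a. The text prints part of the genes this rule names, picked after their values were seen.

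The overlap of both tumor groups' changes was set beside 100 simulations of unchanged groups measured against the same normal arrays. The steps were tested on simulated data drawn for each gene from a normal distribution with its mean and its limma SD, with 200 of 19309 genes changed by known amounts. For log2 changes of 0.5, 1 and 2, the right call was made for 1.49%, 74.6% and 98.5% of changed genes in control tumor against normal thymocytes, for 7.46%, 49.2% and 93.9% in deficient tumor against normal thymocytes, and for 5.97%, 76.1% and 97.0% in deficient against control tumor. Among unchanged genes 5, 6 and 4 were called, and none of 20 unchanged lists. The simulated genes were drawn independently and with the same SD in all groups. The list result therefore does not cover lists whose genes vary together.

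The alternatives were a mean-variance trend with a robust prior, removal of the dimmest 30% or 50% of genes, a second quantile normalization, centring on each array's median, array weights, fits of only the 2 groups compared, the mean of a gene's probe sets, all probe sets, the replicate number as a block, an ordinary linear model, and leaving out each array in turn. After the data were seen, cyclic loess between arrays and fits without control tumors 1 and 2, without 3, 4 and 5, and without 3 and 4 were added, and the scalings were run for the lists too. A sample was singled out where its gap to the nearest other sample of its group exceeded Dixon's critical share of the range (0.829 for 4 arrays, 0.71 for 5). Groups of 3 were not tested in this way.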

Results

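RNA was profiled from the thymus of FVB/N mice on 12 whole-transcript expression arrays. Normal thymocytes came from 3 wild-type samples at 24 days of age. T-cell lymphomas induced by MYC came from animals at the terminal stage: 5 control tumors with intact Dnmt3a and 4 tumors in which Dnmt3a, a de novo DNA methyltransferase, had been deleted in the blood lineage. The labels do not state that each array came from a separate animal, so p-values measure the spread between these samples. An age is given only for the normal thymocytes and may differ together with tumor state. No scan date or batch is given, so neither age nor batch can be told apart from the group. Median log2 values were 6.40 to 6.58 on all 12 arrays, and the number of arrays limits the precision. The 75th percentile was 8.50 to 8.60 in the 4 Dnmt3a-deficient tumors and in control tumors 1 and 2. In the other control tumors and in normal thymocytes it was 8.13 to 8.30.

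The first component of a principal component analysis held 51.4% of the variance and the second 17.2%. Control tumors 1 and 2 had mean correlations of 0.972 and 0.971 with the deficient tumors, against 0.956 and 0.951 with the other control tumors. The single array most similar to control tumor 2 was control tumor 1 (r = 0.9765), and that most similar to control tumor 1 was deficient tumor 1 (0.982). Control tumors 3, 4 and 5 correlated better with other control tumors, at 0.963, 0.960 and 0.956, than with deficient tumors, at 0.949, 0.942 and 0.949. Across genes, the median SD was 0.278 in control tumors (n = 5), 0.186 in normal thymocytes (n = 3) and 0.186 in deficient tumors (n = 4).

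**Figure D1:**
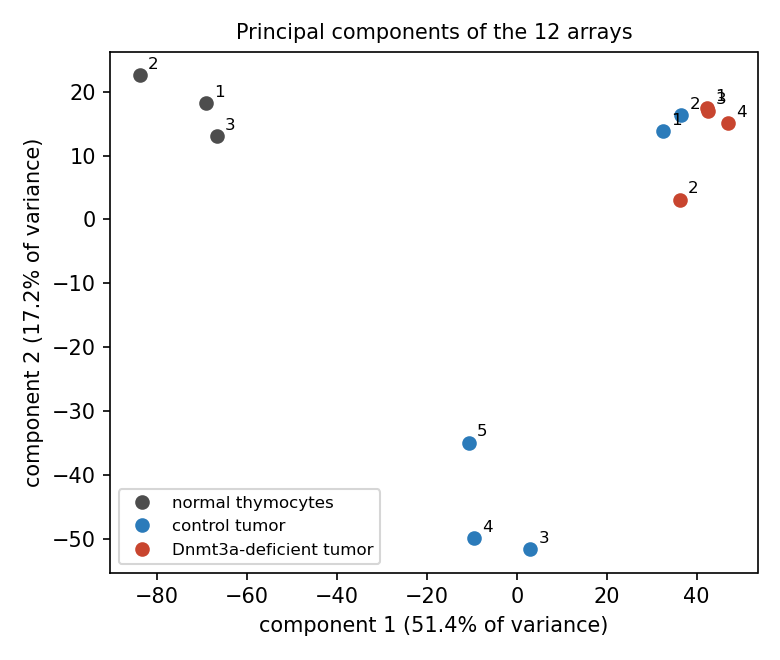
Principal components of the 12 arrays over all genes tested. The axes are scores on component 1 (51.4% of variance) and component 2 (17.2%), each point is an array numbered by replicate and coloured by group, and control tumors 1 and 2 lie near the deficient tumors.

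Dnmt3a itself was measured first, as a check of the labels. Its log2 expression was 9.48 ± 0.15 in normal thymocytes (SD, n = 3), 8.67 ± 0.53 in control tumors (n = 5) and 7.42 ± 0.20 in deficient tumors (n = 4). Every deficient tumor lay below every control tumor (exact two-sided permutation p = 0.00794, the smallest that the 126 splits can give). The deficient tumors differed from the control tumors by -1.25 (SE 0.229, limma adjusted p = 0.0317). The signal was reduced and not absent; whether the probe set lies inside the deleted exons is not given in the sources used here. The adjusted p rose to 0.0658 without control tumor 3, 0.0629 without deficient tumor 1, 0.108 without deficient tumor 3 and 0.0993 without deficient tumor 4, and to 0.105 when the fit held the tumors alone.

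The comparison of control tumors with normal thymocytes asks which genes differ in a MYC-driven lymphoma with intact Dnmt3a. MYC targets of ribosome production were higher in the tumors, and early thymocyte, Notch and interferon response genes were lower. These 4 of the 15 called lists kept their call with an estimated correlation, while those of the cell cycle and of later thymocyte stages did not. The early thymocyte and Notch lists share Hes1, Dtx1, Notch1, Notch3, Il2ra and Ptcra, so their calls are not separate results. Dkc1, which encodes the pseudouridine synthase dyskerin, went from 6.87 ± 0.76 in normal thymocytes (SD, n = 3) to 10.11 ± 0.27 in control tumors (n = 5), a log2 difference of 3.24 (SE 0.267, adjusted p = 3.7e-06). Rag1, which encodes a subunit of the antigen receptor recombinase, went from 11.69 ± 0.13 to 7.71 ± 1.95, a difference of -3.98 (SE 0.977, adjusted p = 0.00904). The mouse Myc gene fell from 9.60 ± 0.23 to 6.65 ± 0.58 (difference -2.95, SE 0.280, adjusted p = 1.0e-05), and Mycn fell by 1.10 (adjusted p = 9.7e-04). The labels do not say which MYC sequence drove the tumors, so this probe set need not measure the transgene.

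Of 19309 genes tested, 4706 were called at an adjusted p under 0.05 with limma, 2519 higher and 2187 lower in control tumors, a majority that turned after a second quantile normalization (2238 higher, 2845 lower). A change of at least 2-fold was found for 2099 of them, 1470 higher and 629 lower. Among the largest increases were Grb10, an imprinted adaptor of growth factor receptors (log2 difference 5.11, SE 0.745), the metallothionein Mt1 (4.02, SE 0.187) and the extracellular proteoglycan Spock2 (3.91, SE 0.506). The largest decreases included Dntt, the terminal transferase that adds nucleotides at receptor gene junctions (-4.79, SE 0.871), Ly6d (-4.14, SE 0.212) and the receptor Ephb6 (-3.84, SE 0.424).

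MYC target genes of ribosome biogenesis and growth rose as a group: 31 of 39 were higher and none was lower (limma camera adjusted p = 9.4e-22; adjusted p = 0.0155 with an estimated correlation). Besides Dkc1 they included the transferrin receptor Tfrc (3.20) and nucleophosmin, Npm1 (2.90). Of 29 genes of G2 and mitosis 15 were higher, among them Bub1 (3.08), Kif11 (3.01) and Mki67 (2.05), with an adjusted p = 4.4e-07 and an adjusted p = 0.175 with an estimated correlation. Of 37 DNA replication genes 13 were higher, among them Pola1 (2.59) and Pole (1.54), with an adjusted p = 5.7e-04 and an adjusted p = 0.230 with an estimated correlation. Adjusted over the list alone, 32, 16 and 13 members of these lists were higher and none was lower. The shift of the replication list was not called after cyclic loess normalization (adjusted p = 0.116).

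Lists of metabolic genes also shifted upward. Glycolysis had 10 of 20 genes higher and 2 lower (Pgam1, 1.51; Tpi1, 1.13; adjusted p = 0.00105, adjusted p = 0.159 with an estimated correlation). Targets of ATF4 in the response to amino acid shortage had 8 of 23 higher, led by asparagine synthetase, Asns (3.82, SE 0.230), with Slc7a5 (1.70) and Psat1 (1.28) (adjusted p = 0.00146, adjusted p = 0.229 with an estimated correlation). Cholesterol synthesis had 6 of 20 higher and 1 lower (Idi1, 2.35; Hmgcs1, 1.42; adjusted p = 0.0189, adjusted p = 0.326 with an estimated correlation). Oxidative phosphorylation had 5 of 31 higher (Cycs, 1.60; adjusted p = 0.0182, adjusted p = 0.318 with an estimated correlation), and its direction turned under cyclic loess normalization, with a median of -0.07. The call of oxidative phosphorylation also ended without control tumor 3 (adjusted p = 0.0533) or normal thymocytes 3 (0.0516) and after a second quantile normalization (0.325), and that of cholesterol synthesis after the same normalization (0.206) or cyclic loess (0.162). With p-values adjusted over the list alone, glycolysis had 10 higher and 3 lower, ATF4 targets 8 higher, cholesterol synthesis 8 higher and 1 lower, and oxidative phosphorylation 5 higher.

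Thymocyte stage genes fell. Of 25 early thymocyte and pre-TCR genes 12 were lower and 1 was higher (adjusted p = 0.00111, adjusted p = 0.0262 with an estimated correlation), including Rag2 (-3.12). Of 16 Notch pathway targets 8 were lower and 1 was higher (adjusted p = 1.8e-05, adjusted p = 0.0262 with an estimated correlation), including Notch1 (-2.44), the cyclin Ccnd3 (-2.25), the pre-TCR alpha chain Ptcra (-1.73) and Dtx1 (-1.65). Of 21 genes of the double-positive stage 11 were lower and 1 was higher, including Bcl2l1 (-3.26) and Arpp21 (-3.20) (adjusted p = 0.00111, adjusted p = 0.285 with an estimated correlation). Among genes of mature T cells 10 of 30 were lower, including Nkg7 (-2.87) (adjusted p = 0.00338, adjusted p = 0.285 with an estimated correlation). Among T cell receptor signaling genes 10 of 30 were lower and 1 was higher, including Cd247 (-1.38) and Lat (-1.07) (adjusted p = 0.00189, adjusted p = 0.230 with an estimated correlation). The lower members numbered 13, 10, 14, 10 and 10 in these lists, and the higher members 3, 1, 2, 0 and 1, when adjusted over the list alone. The lineage marker Cd8a was lower by log2 -2.49 (SE 0.795, adjusted p = 0.0365), and not called when single arrays were left out in 4 of 8 fits, with an adjusted p of up to 0.102 without normal thymocytes 2. Cd4 (-0.93, adjusted p = 0.105) and Cd3e (-0.67, adjusted p = 0.0875) did not pass the threshold, though leaving out 1 array gave adjusted p-values down to 0.0413 and 0.0190.

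Interferon response genes were lower: 16 of 31 fell and none rose (adjusted p = 2.3e-07, adjusted p = 0.0262 with an estimated correlation), with Rtp4 at -2.81 (SE 0.296) and the transcription factor Irf7 at -2.05 (SE 0.190). Of 15 genes of MHC and antigen presentation 6 were lower, including Tapbp (-1.75) and Tap1 (-1.32) (adjusted p = 0.00105, adjusted p = 0.230 with an estimated correlation). The BCL2 family and cell death list had 8 of 24 lower and 5 higher (adjusted p = 0.0298, adjusted p = 0.128 with an estimated correlation), with the pro-apoptotic Bmf at -2.24 and the death receptor Fas at -1.74 among the lower. The BCL2 call ended without normal thymocytes 1 (adjusted p = 0.0667). Counts adjusted over the list alone were 17, 8 and 10 lower and 1, 0 and 5 higher.

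In 5 lists no shift was called between control tumors and normal thymocytes. DNA methylation machinery had 7 of 24 higher, such as the chromatin remodeler Hells (2.43) and the dioxygenase Tet2 (1.64), and 5 lower (adjusted p = 0.375). Dnmt3a was lower by log2 -0.82 (SE 0.249, adjusted p = 0.0295), a call found in 1 of 8 fits that left out an array (adjusted p up to 0.105, without normal thymocytes 1). Dnmt3b differed by 0.03 (SE 0.220) and the maintenance enzyme Dnmt1 by 0.15 (SE 0.147), neither called. Polycomb and histone modifiers had 10 of 24 higher, such as Suz12 (2.23) and Setd2 (1.87), and 6 lower (adjusted p = 0.105). Targets of p53 had 1 of 22 higher, Ccng1 (2.39), and 3 lower (adjusted p = 0.729). Germline genes silenced by methylation had 2 of 28 lower (adjusted p = 0.156), and imprinted genes 4 of 26 higher and 1 lower (adjusted p = 0.607), with Airn (1.78) and Impact (1.77) besides Grb10 among the higher. These lists had 8 higher and 6 lower, 10 and 6, 1 and 3, 0 and 1, and 4 and 1 when adjusted over the list alone. The median and the mean differed in sign for DNA methylation machinery (-0.00 and 0.28), imprinted genes (-0.01 and 0.38) and p53 targets (0.09 and -0.00), where the test pointed upward.

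None of the 9 marker lists of other cell types was called between control tumors and normal thymocytes. Their median differences were 0.33 for macrophages (adjusted p = 0.170, with Itgam higher by 1.22), 0.42 for adipocytes (adjusted p = 0.344), -0.03 for neutrophils (mean 0.02, adjusted p = 0.700), -0.05 for fibroblasts and endothelium (adjusted p = 0.700), -0.18 for NK cells (adjusted p = 0.309), -0.21 for erythroid cells (adjusted p = 0.197, with Car2 lower by log2 -2.13), -0.28 for B cells (adjusted p = 0.309), -0.33 for dendritic cells (adjusted p = 0.197) and -0.44 for thymic epithelium (adjusted p = 0.0895). At most 3 members of a marker list were called in either direction, and at most 4 when adjusted over the list alone. Without control tumor 5 the macrophage list (median 0.59, adjusted p = 0.0361) and the thymic epithelium list (-0.51, adjusted p = 0.0494) were called. The neutrophil marker mean was 7.76 in control tumor 3 and 7.65 in control tumor 4, against 6.27 to 6.70 in normal thymocytes and 5.61 to 5.94 in the other control tumors. The adipocyte marker mean was 7.95 in control tumor 2 and 5.16 to 5.33 in the other control tumors.

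The comparison of Dnmt3a-deficient tumors with normal thymocytes asks the same of lymphomas that lacked the enzyme. MYC targets of ribosome production were higher, the only 1 of 15 called lists that kept its call with an estimated correlation. The lists of mitosis and DNA replication (higher) and of T cell development and receptor signaling (lower) lost theirs in that test. Bub1, a mitotic checkpoint kinase, rose from 6.24 ± 0.79 in normal thymocytes (SD, n = 3) to 10.39 ± 0.15 in deficient tumors (n = 4), a log2 difference of 4.15 (SE 0.441, adjusted p = 1.4e-05). The chemokine receptor Ccr9 fell from 11.25 ± 0.21 to 7.08 ± 1.34, a difference of -4.17 (SE 0.824, adjusted p = 0.00156). Dnmt3a differed by -2.06 (SE 0.261, adjusted p = 5.3e-05), and Myc by -3.19 (SE 0.293, adjusted p = 4.8e-06).

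Limma called 7262 genes, 3602 higher and 3660 lower, a balance that depends on the scaling: 3754 and 3024 after median centring, 2968 and 3834 after a second quantile normalization, and 3439 and 2006 without the dimmest 50% of genes. Of the 7262 genes 3240 changed at least 2-fold, 2286 upward and 954 downward. The metallothioneins Mt2 (6.32, SE 0.767) and Mt1 (4.66, SE 0.195), the adenylate kinase Ak4 (5.15, SE 0.644), the telomerase RNA Terc (4.59, SE 1.01) and the import receptor Ipo7 (4.36, SE 0.415) were among the largest increases. Ephb6 (-4.36), Rag1 (-4.28), Ly6d (-4.24), Itm2a (-4.02), Dntt (-4.00) and Cd6 (-3.62) were among the largest decreases. Mycn was lower by log2 -1.27 (SE 0.202).

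MYC targets were higher in 32 of 39 cases and lower in none (adjusted p = 9.4e-17, adjusted p = 0.0372 with an estimated correlation), with nucleolin, Ncl (3.13), Hspd1 (2.94) and Gnl3 (2.81). Genes of G2 and mitosis were higher in 22 of 29 cases (adjusted p = 3.2e-09, adjusted p = 0.138 with an estimated correlation), with Kif11 (3.88), Cenpe (3.53) and Mki67 (2.87). DNA replication genes were higher in 17 of 37 cases (adjusted p = 6.6e-06, adjusted p = 0.160 with an estimated correlation), with Pola1 (3.11) and the cyclin Ccne2 (2.58). Polycomb and histone modifiers had 12 of 24 higher, such as Suz12 (2.86), and 5 lower, such as Kdm5b (-2.20) (adjusted p = 0.0354, adjusted p = 0.282 with an estimated correlation). The Polycomb call ended after a second quantile normalization (adjusted p = 0.296) or cyclic loess (0.560). The higher members numbered 33, 22, 18 and 13, and the lower members 1, 0, 2 and 6, when adjusted over the list alone.

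Glycolysis had 11 of 20 genes higher and 3 lower (adjusted p = 0.00978, adjusted p = 0.230 with an estimated correlation), with Pgam1 at 2.13 and Ldhb at -3.58. ATF4 targets had 9 of 23 higher (adjusted p = 0.00983, adjusted p = 0.273 with an estimated correlation), with Asns at 4.05 and Mthfd2 at 2.08. Oxidative phosphorylation had 12 of 31 higher and 3 lower (adjusted p = 0.0359, adjusted p = 0.380 with an estimated correlation), with cytochrome c, Cycs, at 2.79 and Atp5g1 at 2.45, and turned direction under cyclic loess normalization (median -0.04). Cholesterol synthesis had 8 of 20 higher and 2 lower (adjusted p = 0.0397, adjusted p = 0.393 with an estimated correlation), with Idi1 at 1.96 and Hmgcs1 at 1.65. The higher and lower members were 11 and 5, 9 and 0, 12 and 4, and 8 and 2 when adjusted over the list alone. Without deficient tumor 4 or normal thymocytes 3 oxidative phosphorylation had an adjusted p of 0.0564 or 0.0633 and cholesterol synthesis 0.0917 or 0.0633, and the latter 0.0585 without deficient tumor 3. A second quantile normalization gave an adjusted p of 0.491 for oxidative phosphorylation, 0.485 (0.498 under cyclic loess) for cholesterol synthesis and 0.0981 (0.245) for glycolysis, and cyclic loess 0.0533 for ATF4 targets.

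Early thymocyte genes had 12 of 25 lower and 1 higher (adjusted p = 0.00650, adjusted p = 0.0683 with an estimated correlation), and Notch targets 10 of 16 lower and 1 higher (adjusted p = 4.5e-04, adjusted p = 0.0683 with an estimated correlation), with Notch3 at -1.78 and Ccnd3 at -2.25. Double-positive stage genes had 11 of 21 lower and 1 higher (adjusted p = 0.00116, adjusted p = 0.282 with an estimated correlation), with Bcl2l1 at -3.35 and Cd2 at -3.21. Mature T cell genes had 13 of 30 lower (adjusted p = 8.5e-04, adjusted p = 0.238 with an estimated correlation), with Gimap6 at -2.74. T cell receptor signaling genes had 17 of 30 lower and 1 higher (adjusted p = 8.6e-04, adjusted p = 0.230 with an estimated correlation), with Cd5 at -1.97 and Egr2 at -1.93. MHC genes had 7 of 15 lower and 1 higher (adjusted p = 0.0402, adjusted p = 0.409 with an estimated correlation), with H2-Q4 at -2.56 and the class II gene H2-Eb1 at 1.33. Germline genes had 4 of 28 lower (adjusted p = 0.0247, adjusted p = 0.107 with an estimated correlation), among them Dppa3 (-1.57), at 4.08 ± 0.04 in deficient tumors (n = 4), below the 25th percentile of each array (5.09 to 5.32). The call of the MHC list ended without deficient tumor 3 (adjusted p = 0.0585) or normal thymocytes 1 (0.0862), and that of the germline list after a second quantile normalization (0.225) or cyclic loess (0.245). Adjusted over the list alone, the lower members of these 7 lists numbered 12, 12, 12, 14, 17, 7 and 2, and the higher members 2, 1, 1, 0, 1, 1 and 0. Cd4 was lower by log2 -1.76 (SE 0.412, adjusted p = 0.00475), while Cd8a (-2.11, adjusted p = 0.0617) and Cd3e (-0.15, adjusted p = 0.705) were not called.

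No shift was called for the interferon list (4 of 31 higher, 10 lower, adjusted p = 0.192), where Rtp4 differed by -1.58, Irf7 by -1.45 and Zbp1 by -1.39. The same held for DNA methylation machinery (9 of 24 higher, 4 lower, adjusted p = 0.0896), where Hells (2.32) and Tet2 (1.96) were called higher and Gadd45a lower. Dnmt3b was higher by 0.66 (SE 0.230, adjusted p = 0.0368), a call found in 2 of 7 fits that left out an array (adjusted p up to 0.106, without normal thymocytes 3). The BCL2 family (4 of 24 higher, 10 lower, adjusted p = 0.0753), p53 targets (5 of 22 higher, 4 lower, adjusted p = 0.985) and imprinted genes (3 of 26 higher, including Airn at 3.11, and 4 lower, adjusted p = 0.740) were not called either. The BCL2 list was called without normal thymocytes 2 (median -0.46, adjusted p = 0.0435), after a second quantile normalization (0.0219) and after cyclic loess (0.0368). In the order given, these lists had 4 higher and 10 lower, 10 and 4, 4 and 10, 5 and 4, and 2 and 2 when adjusted over the list alone. The median of imprinted genes was -0.19 and their mean 0.19.

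None of the 9 marker lists was called between deficient tumors and normal thymocytes. The median differences were 0.49 for macrophages (adjusted p = 0.196, with Fcgr3 higher by 1.41), -0.70 for neutrophils (adjusted p = 0.196), -0.32 for erythroid cells (adjusted p = 0.196), -0.22 for dendritic cells (adjusted p = 0.268), -0.21 for thymic epithelium (adjusted p = 0.268), -0.08 for adipocytes (adjusted p = 0.822), -0.04 for B cells (adjusted p = 0.822), 0.01 for NK cells (mean -0.21, adjusted p = 0.810) and 0.01 for fibroblasts and endothelium (mean 0.09, test downward, adjusted p = 0.822). At most 5 members of a marker list were called in either direction, in both counts.

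The tumor groups shared part of their differences from normal thymocytes. Of the genes called in each, 2300 were higher in both (91.3% of the control tumors' higher genes and 63.9% of the deficient tumors') and 1796 were lower in both (82.1% and 49.1%). Independent lists of these sizes would share 469.9 and 414.5, numbers that ignore the shared normal arrays. Opposite calls were found for 3 genes. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.884, against 0.598 in 100 simulations of unchanged groups measured against the same normal arrays. The covariance was 0.497 against a simulated 0.0342, and 83.6% of genes had the same sign against 70.4%. The 3 normal arrays are too few to split, and the simulated values stand for what sharing them gives.

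The direct comparison of the tumor groups asks what differs in lymphomas that lacked Dnmt3a. Interferon response genes were higher in the deficient tumors, and small groups of single genes differed in both directions. Gadd45b, a stress response gene, was 7.19 ± 0.26 in control tumors (SD, n = 5) and higher in deficient tumors (n = 4) by log2 1.80 (SE 0.240, adjusted p = 0.0144). Dusp6, a phosphatase that inactivates ERK, was 6.70 ± 0.12 in deficient and 9.15 ± 0.60 in control tumors, a difference of -2.44 (SE 0.244, adjusted p = 0.00312). Cd79b, a subunit of the B cell receptor, differed by 1.63 (SE 0.215) and the cannabinoid receptor Cnr2 by -1.65 (SE 0.238), both with an adjusted p = 0.0144.

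Limma called 158 genes, 114 higher (72.2%) and 44 lower, of which 96 changed at least 2-fold, 68 upward and 28 downward. A second quantile normalization gave 57 higher of 102 (55.9%), cyclic loess 86 of 142 (60.6%) and median centring 258 of 306 (84.3%). The majority turned to 17 higher and 65 lower without control tumors 3, 4 and 5, a fit chosen after the data were seen, and was 84 to 71 without control tumor 5. The count depended on the fit and on single arrays: it was 1, Dusp6, when only the tumors were fitted, 0 with an ordinary linear model (limma gave 3897 genes with an unadjusted p under 0.05), and 28, 36, 33 and 16 without control tumor 3, control tumor 4, deficient tumor 3 or deficient tumor 4. Without control tumor 1 or control tumor 2, which lay near the deficient tumors, it was 1012 or 1482, and without deficient tumor 1 it was 102. In all 9 fits that left out a tumor, 12 of the 158 genes were called.

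Those 12 included Gadd45b, Dusp6, Cd79b and Cnr2, the peptidylarginine deiminase Padi4 (2.21, SE 0.324), the U3 small nucleolar RNA Rnu3a (2.31, SE 0.296) and the small nucleolar RNA Snora33 (1.95, SE 0.282). Of the 12, only Dusp6 was called when the tumors alone were fitted, and none with an ordinary linear model. Other genes with large differences lost their call in at least 1 of the 9 fits. The aminopeptidase Rnpep (2.24, adjusted p = 0.0144), the zinc finger gene Rsl1 (2.16, adjusted p = 0.0193) and Shisa6 (-1.76, adjusted p = 0.0144) reached 0.0619, 0.0744 and 0.0552 without deficient tumor 4. Gphn (2.15), Mb21d2 (-1.64) and Ctse (-1.54) reached 0.109, 0.0744 and 0.0908 without the same tumor, and Snord118 (3.25, SE 0.670, adjusted p = 0.0477) reached 0.132. Grb10 (-3.44, SE 0.684, adjusted p = 0.0442) and Palmd (-2.57, SE 0.491, adjusted p = 0.0380) reached 0.140 and 0.118 without deficient tumor 3.

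The interferon list was higher in deficient tumors in 28 of 31 members by sign, with a median of 0.60 (limma camera adjusted p = 5.0e-11; adjusted p = 0.0264 with an estimated correlation). Over all genes 4 members were called and none was lower, and 17 were higher when adjusted over the list alone. The 4 were Usp18, which removes ISG15 from proteins (1.91, SE 0.296), the GTPase Irgm1 (1.59, SE 0.268), Oas2 (1.03, SE 0.214) and Rsad2 (0.86, SE 0.162), and without deficient tumor 4 their adjusted p rose to 0.0744, 0.0848, 0.148 and 0.128. The related gene Ifi203, outside the list, was higher by 2.00 (adjusted p up to 0.0843, without control tumor 3). The mean of the list was 6.97 ± 0.13 in deficient tumors (n = 4), 6.38 ± 0.10 in control tumors (n = 5) and 7.24 ± 0.09 in normal thymocytes (n = 3). All 4 deficient tumors lay above all 5 control tumors (exact two-sided permutation p = 0.00794, adjusted 0.0529 over the 20 lists). The adjusted value is set by how many lists reach the smallest p, here the interferon, DNA replication and germline lists. A list that reached it alone could not have passed 0.05 after adjustment. The macrophage and dendritic cell marker means differed by 0.14 (exact two-sided p = 0.690) and -0.07 (exact two-sided p = 0.587).

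Genes of G2 and mitosis had a median difference of 0.47 with 25 of 29 positive and none called (adjusted p = 7.8e-06, adjusted p = 0.412 with an estimated correlation), and 4 were higher when adjusted over the list alone. DNA replication had a median of 0.27 with 28 of 37 positive (adjusted p = 9.2e-05, adjusted p = 0.412 with an estimated correlation). Its call ended without control tumors 1 and 2 (adjusted p = 0.200), left out after the data were seen, while those of the interferon and mitosis lists were kept. Mitosis means were 9.70 and 9.56 in these 2 arrays, 9.01 to 9.42 in the other control tumors and 9.75 to 9.95 in deficient tumors. Interferon means were 6.37 and 6.55 in them and 6.28 to 6.40 in the other control tumors. Leaving them out widened both differences, so the kept calls are no check on these lists. In the replication list Ccne2 was called (1.21, adjusted p = 0.0453, up to 0.148 without deficient tumor 3), and 9 were higher when adjusted over the list alone. Birc5, with the smallest p of the mitosis list, differed by 0.62 (adjusted p = 0.0945, down to 0.0384 with 1 tumor left out). The array means of mitosis genes gave an exact two-sided p = 0.0159 and those of replication genes an exact two-sided p = 0.00794, adjusted 0.0794 and 0.0529.

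Mature T cell genes were lower, with a median of -0.40 and 1 of 30 called (adjusted p = 0.0360, adjusted p = 0.730 with an estimated correlation), namely the costimulatory receptor Cd27 (-1.30, adjusted p = 0.0477, up to 0.168 without deficient tumor 4). T cell receptor signaling genes had a median of -0.24 with none of 30 called (adjusted p = 0.0422, adjusted p = 0.730 with an estimated correlation), and Cd5 differed by -1.45 (adjusted p = 0.0861, down to 0.0164 with 1 tumor left out). When adjusted over the list alone, 5 and 2 members were lower. The array means of these lists gave an exact two-sided p = 0.246 and 0.159 (adjusted 0.635 and 0.529), and the mature T cell mean of deficient tumor 2 (8.38) lay above all control tumors (7.64 to 8.19). The call of the mature list ended without control tumor 3 (adjusted p = 0.0638) or 4 (0.0648), and without deficient tumor 1 (0.112), 3 (0.120) or 4 (0.104). The call of the signaling list ended without control tumor 1 (0.164) or 4 (0.0881), and without deficient tumor 1 (0.0757) or 3 (0.241). Without both control tumors 1 and 2 the calls of the mature (0.0528), signaling (0.200) and germline lists (0.0958) ended. Germline genes silenced by methylation were lower, by a median of -0.14, with none of 28 called in either count (adjusted p = 0.0319, adjusted p = 0.133 with an estimated correlation), a call that ended after a second quantile normalization (adjusted p = 0.128) or cyclic loess (0.192). Their array means were 4.65 ± 0.03 in deficient tumors (n = 4) and 4.81 ± 0.04 in control tumors (n = 5), below the 25th percentile of each array (5.09 to 5.32) (exact two-sided p = 0.00794, adjusted 0.0529), and Dppa3 differed by -0.44 (adjusted p = 0.109).

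Neutrophil markers were lower in deficient tumors, by a median of -0.98 with none of 14 called and 3 lower when adjusted over the list alone (adjusted p = 6.1e-05, adjusted p = 0.890 with an estimated correlation). Mmp9 differed by -1.08 (adjusted p = 0.0648, down to 0.0208 with 1 tumor left out). Control tumors 3 and 4 had marker means of 7.76 and 7.65, while the other tumors of both groups had 5.38 to 6.01 (exact two-sided p of the array means 0.190, adjusted 0.777 over the marker lists). Without control tumors 3 and 4, left out after the data were seen, the median was -0.12 (adjusted p = 0.322), the mature T cell list had a median of -0.05 (adjusted p = 0.244), and the interferon list kept 0.52 (adjusted p = 8.4e-12).

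The other lists were not called. DNA methylation machinery had Gadd45b higher and Dnmt3a lower (adjusted p = 0.226), with Dnmt3b at 0.63 (SE 0.202, adjusted p = 0.127, exact two-sided permutation p = 0.0317), Dnmt1 at 0.25 (adjusted p = 0.311) and Gadd45a at -0.82 (adjusted p = 0.0607, down to 0.0120 with 1 tumor left out). Polycomb and histone modifiers had 1 of 24 called, Cbx7 (1.25), with an adjusted p = 0.215, and MYC targets 1 of 39, Nop16 (0.70), with an adjusted p = 0.163. Early thymocyte genes had Notch1 higher (0.98) and Gata3 lower (-1.08), with an adjusted p = 0.999, Notch targets 1 of 16 higher, Notch1 itself (adjusted p = 0.830), and double-positive stage genes 1 of 21 lower, Tespa1 (-1.14), with an adjusted p = 0.366. The BCL2 family had Cflar lower (-1.08; list adjusted p = 0.830), MHC genes had H2-Eb1 higher (1.31; list 0.478), glycolysis had the glucose transporter Slc2a3 lower (-0.94; list 0.830), and imprinted genes had Grb10 lower (list 0.163). Of p53 targets (0.811), oxidative phosphorylation (0.811), cholesterol synthesis (0.999) and ATF4 targets (0.830) no member was called. Cbx7, Gata3, H2-Eb1, Nop16, Slc2a3 and Cd27 reached an adjusted p of 0.0793, 0.0744, 0.0744, 0.136, 0.139 and 0.168 without deficient tumor 4. Notch1 and Cflar reached 0.163 and 0.137 without deficient tumor 3, and Tespa1 0.119 without control tumor 3.

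Members higher and lower, adjusted over the list alone, were 2 and 2 for DNA methylation machinery, 2 and 1 for Polycomb, 1 and 0 for MYC targets, 1 and 2 for early thymocyte genes, 1 and 2 for double-positive stage genes, 1 and 0 for Notch targets, 1 and 0 for p53 targets and 1 and 2 for the BCL2 family. They were 2 and 0 for MHC genes, 1 and 2 for imprinted genes, 3 and 1 for glycolysis, 4 and 0 for oxidative phosphorylation, and 0 and 0 for cholesterol synthesis and for ATF4 targets. Median, mean and test differed in sign for early thymocyte genes (0.05, 0.05, downward), Notch targets (-0.09, 0.03, upward), p53 targets (0.02, -0.05, downward) and the BCL2 family (-0.04, 0.01, downward). Myc (-0.24), Mycn (-0.17), Cd3e (0.52), Cd4 (-0.82) and Cd8a (0.38) were not called, with an adjusted p of 0.619, 0.614, 0.255, 0.224 and 0.801. Of the other marker lists, B cells (median 0.04, with Cd79b higher, adjusted p = 0.683), thymic epithelium (0.04, with Cldn4 higher by 1.38, adjusted p = 0.489), NK cells (0.11, adjusted p = 0.746), macrophages (0.03, adjusted p = 0.919), erythroid cells (-0.12, adjusted p = 0.489), dendritic cells (-0.11, adjusted p = 0.811), fibroblasts and endothelium (0.01, test downward, adjusted p = 0.919) and adipocytes (-0.64, adjusted p = 0.0831) were not called. Cldn4 reached an adjusted p of 0.0744 without deficient tumor 4. Adipocyte markers were called without control tumor 3, 4 or 5 (adjusted p = 0.0328, 0.0240 and 0.0192). Their mean was 7.95 in control tumor 2, 5.16 to 5.33 in the other control tumors and 5.12 to 5.37 in deficient tumors. The exact two-sided p of these array means was 0.643 (adjusted 0.777 over the marker lists). Double-positive stage genes were called without control tumor 5 (0.0355) or deficient tumor 1 (0.0487). MYC targets were called without control tumor 3 (0.0247) or deficient tumor 1 (0.0487), and imprinted genes without control tumor 3 (0.0491).

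**Figure D2:**
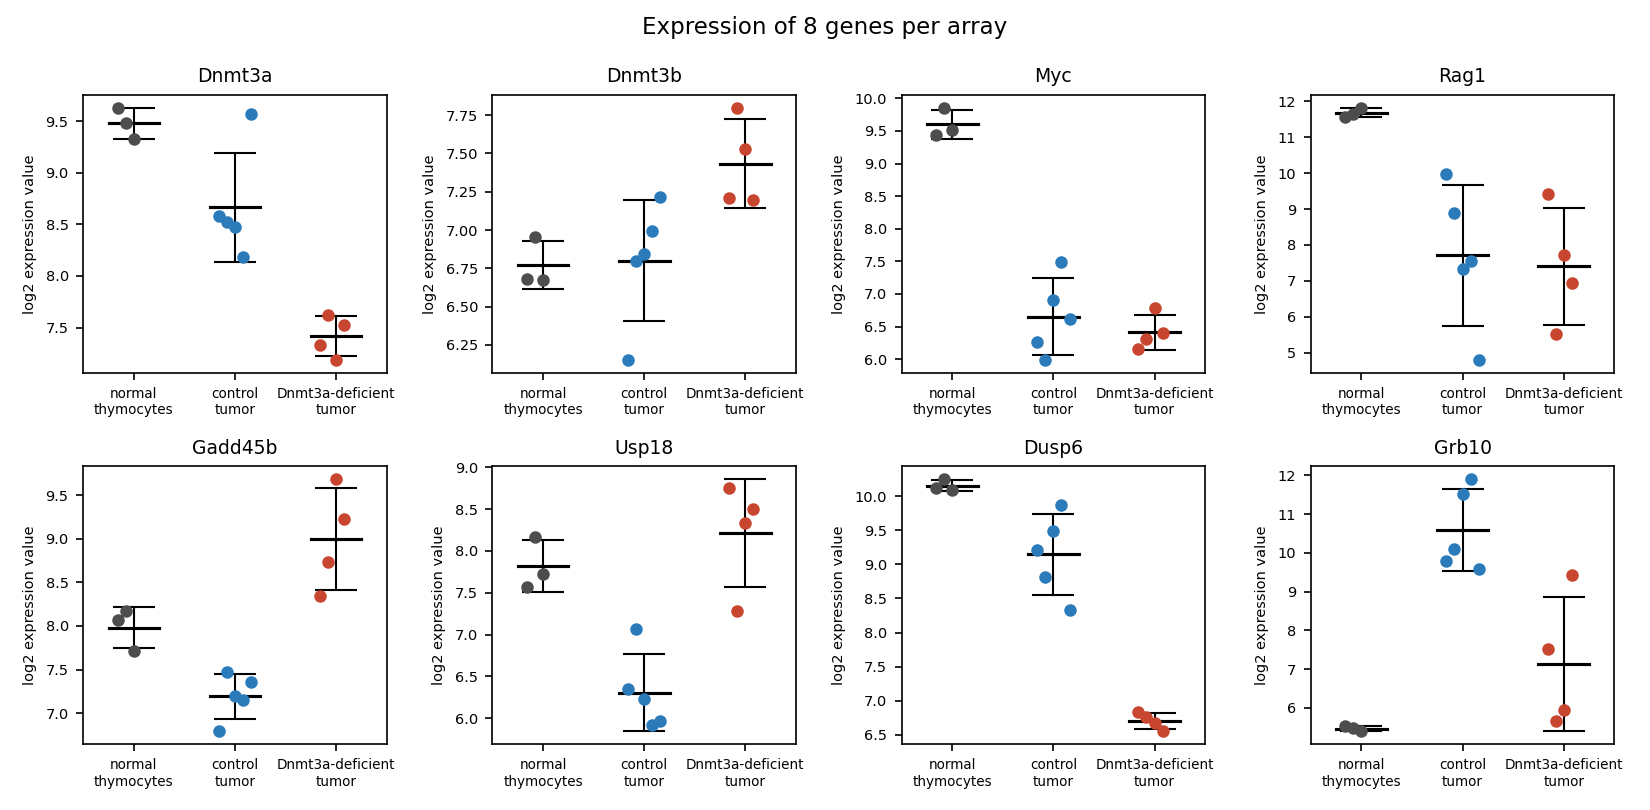
Log2 expression of Dnmt3a, Dnmt3b, Myc, Rag1, Gadd45b, Usp18, Dusp6 and Grb10, where each point is an array, horizontal bars are group means, error bars are 1 SD (n = 3, 5 and 4) and the vertical axes do not start at 0. Dnmt3a had a mean of 9.48 in normal thymocytes, 8.67 in control tumors and 7.42 in deficient tumors.

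**Figure D3:**
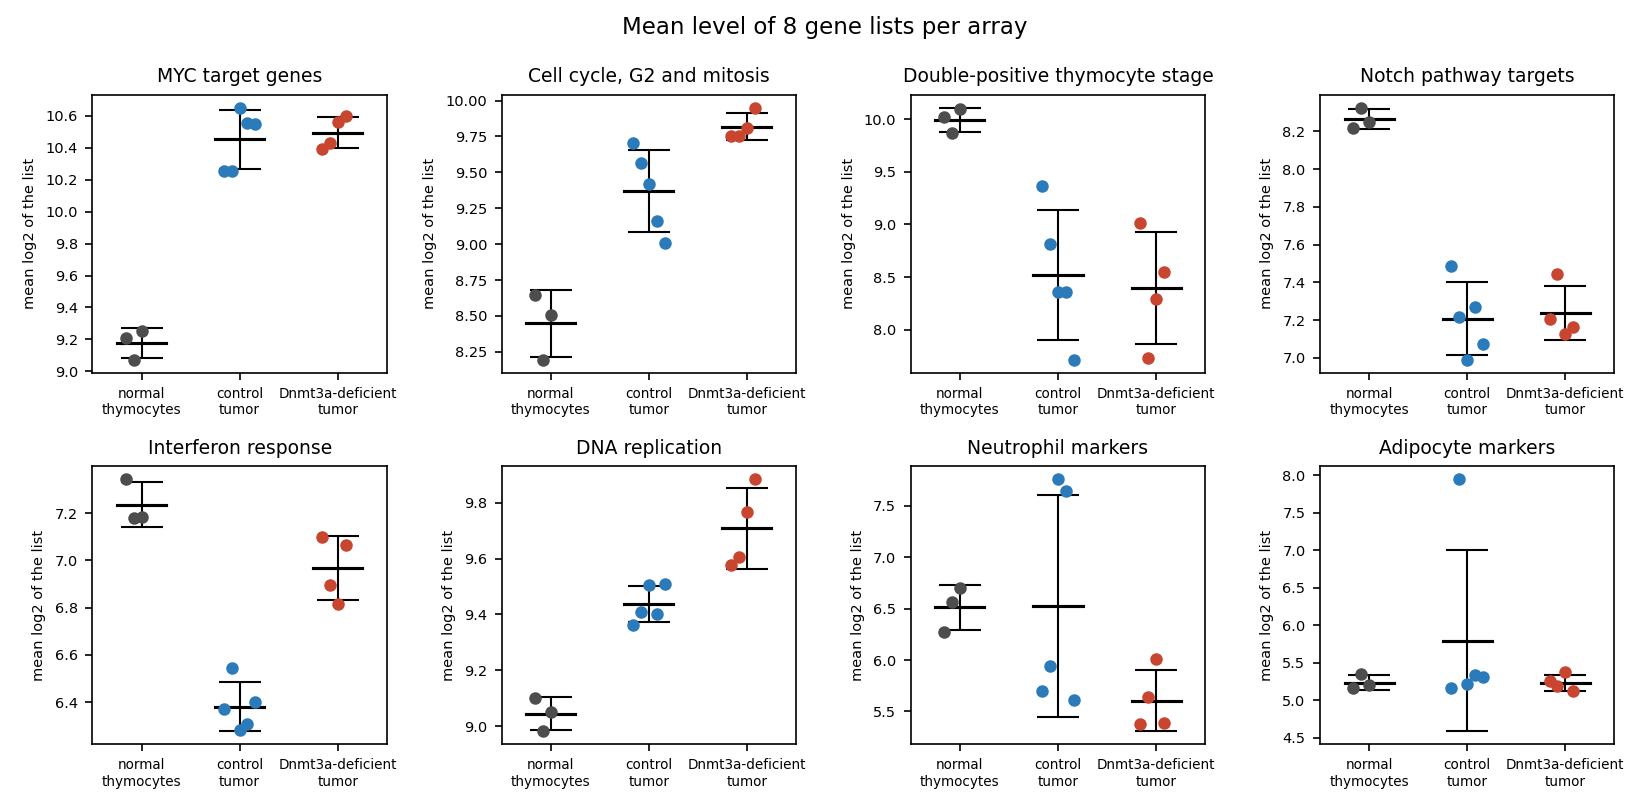
Mean log2 expression of 8 gene lists, where each point is an array, horizontal bars are group means, error bars are 1 SD (n = 3, 5 and 4) and the vertical axes do not start at 0. The interferon mean was 6.97 in deficient and 6.38 in control tumors, and neutrophil markers stood at 7.76 and 7.65 in control tumors 3 and 4.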

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

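The tests of Dnmt3a in control tumors 1 and 2, of neutrophil markers in control tumor 5, of the small RNA level in control tumors 1 and 2, and of macrophage and dendritic cell markers beside the interferon list were chosen after the result was seen.

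Of 286 group values examined, 17 had an array far from the others of its group, where chance gives about 1 in 20. Among genes of the DNA methylation list, Dnmt3a was 9.57 in control tumor 5 against 8.19 to 8.58 in the other control tumors, and Dnmt1 was 10.70 in control tumor 4 against 10.86 to 10.88. Among genes of T cells, Ephb6 was 8.54 in control tumor 1 against 6.81 to 7.29. In deficient tumor 2, Cd8a was 8.23 against 10.98 to 11.37 in the other deficient tumors, Arpp21 5.66 against 8.69 to 9.24, and Cd6 9.12 against 7.09 to 7.28. The mean of mature T cell genes in the same tumor was 8.38 against 7.25 to 7.44. Rsad2 was 6.31 in it against 6.84 to 6.87, Cbx7 8.20 against 8.81 to 8.87, and Cldn4 7.97 against 8.48 to 8.52. In deficient tumor 1, Bcl2l1 was 8.51 against 7.02 to 7.20, Nop16 10.87 against 11.10 to 11.14, and the mean of oxidative phosphorylation genes 10.10 against 10.33 to 10.36. Cflar was 6.19 in deficient tumor 3 against 6.80 to 6.89. Rsl1 was 4.59 in control tumor 4 against 5.81 to 6.20. The macrophage gene Fcgr3 was 6.68 in control tumor 2 against 5.92 to 6.07, and the mean of adipocyte markers 7.95 in the same tumor against 5.16 to 5.33.

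Probe sets without a single gene symbol were outside the comparisons. Between deficient and control tumors, 52 of the 1453 with several symbols were higher and 2 lower, and 29 of the 1535 with none were higher and 8 lower. These limma p-values were adjusted within each kind of probe set alone, so the counts do not compare with those over all genes.

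Control tumors 1 and 2 correlated better with the deficient tumors than with the other control tumors, by a gap of mean correlations of at least 0.0163. Against mislabelled samples, the lower of their Dnmt3a levels lay log2 0.90 above the highest deficient tumor, where the SD of the deficient tumors was 0.195. Against brightness-dependent differences between arrays, the smaller gap was 0.0149 after cyclic loess, 91.2% of its size. Granulocytes in control tumors 3 and 4 may add to the distance of those arrays (marker means 7.76 and 7.65), but control tumor 5, which also lay apart, had a mean of 5.61, below the highest of the 6 arrays on the other side (6.01). A difference in RNA preparation or array batch, and a difference between the tumors themselves, stay open, and no biological explanation besides granulocyte content was tested.

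Small nuclear and nucleolar RNA genes, a family picked after the data were seen, were higher in the deficient tumors by a median of log2 0.58, with 10 of 56 called, none lower and 43 positive (exact two-sided permutation p of their mean 0.00794). Brightness-dependent differences between arrays are argued against as the whole cause by a median of 0.43 after cyclic loess (exact two-sided permutation p = 0.00794). Host genes, taken as the smallest measured gene around each RNA without regard to strand, had a median of -0.20 over 28 pairs. The RNAs of these pairs had a median of 0.64 (RNA minus host 0.63, sign-flip permutation p = 0.00026). That p treats the pairs as replicates, though all were measured on the same tumors, and does not measure the spread between tumors. The host median did not rise with that of the RNAs, but transcription of the hosts was not measured and stays open. Means of this family were at most 8.74 in control tumors 1 and 2 and 8.49 to 8.70 in the other control tumors. They were 9.06 to 9.39 in deficient tumors and 8.21 to 8.51 in normal thymocytes. The family was picked after the data were seen, and its exact p already places every control tumor below the deficient tumors. These means therefore cannot decide whether the likeness of control tumors 1 and 2 to the deficient tumors bears on this family. A difference in how short RNA was kept during preparation, which is confounded with the group, and the loss of Dnmt3a stay open, the latter untested.

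Interferon response genes were higher in the deficient tumors, with a median of 0.60. The marker mean of dendritic cells differed by -0.07 (95% interval -0.354 to 0.221), below the interferon difference of 0.59 (0.400 to 0.774). That of macrophages differed by 0.14 (-0.544 to 0.826). Setting these intervals side by side assumes that markers would shift by as much as interferon genes, which was not tested. They therefore cannot decide whether transcripts of either cell type account for the interferon difference. Of the 28 higher members, 1 lay among the 200 nearest tested genes on either side of Dnmt3a. The list was fixed beforehand and gene positions do not depend on the data. This count therefore cannot decide on a strain variant carried along with Dnmt3a. Brightness-dependent differences between arrays are argued against as the whole cause by a median of 0.52 after cyclic loess (exact permutation p = 0.00794). Macrophages and dendritic cells stay open. A strain variant linked to Dnmt3a, a difference in housing or sample handling and the loss of Dnmt3a also stay open and were untested.

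Other divisions of the same arrays bear on the counts of called genes. Between control tumors and normal thymocytes, 1 of 56 splits, the real one, reached its 4706 genes, and the highest other gave 2015. Between deficient tumors and normal thymocytes, 1 of 35 splits, the real one, reached its 7262 genes, and the highest other gave 1017. Chance is an unlikely source of these counts, but so few splits cannot exclude it. Between the tumor groups, 5 of 100 splits, the real one included, reached its 158 genes, so chance cannot be excluded for that count. The highest other split gave 1876 genes with control tumor 2 set beside the 4 deficient tumors, several times the real count, which points to a structure of the samples.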

How the results depend on the processing

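Cyclic loess, the fits without control tumors 1 and 2, without 3, 4 and 5, and without 3 and 4, and the scalings of the lists were chosen after the result was seen. The other alternatives were planned.

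Counts of called genes against normal thymocytes stayed within 1.5 times under every alternative run, at 3199 to 6854 for control tumors and 5409 to 9127 for deficient tumors (the highest over all probe sets). The comparison of the tumor groups was far less stable: 89 values of its counts, list shifts, Dnmt3a and Dnmt3b kept their side or stayed within 1.5 times, 39 moved and 8 lost the threshold. Named genes kept direction and side of the threshold in 733 alternative values between the tumor groups, 1046 between deficient tumors and normal thymocytes and 1243 between control tumors and normal thymocytes. In the same order 262, 7 and 20 lost the threshold in the same direction, 22, 6 and 10 gained it, and 7, 0 and 9 changed direction. For lists the kept values were 456, 365 and 499, those that lost the threshold 34, 40 and 27, those that gained it 22, 13 and 11, and those that turned 68, 17 and 14. The lowest values of the arrays were 2.4 to 2.72, and the germline list, with array means of 4.61 to 4.99, lies below their 25th percentiles of 5.09 to 5.32. The cause of the changes given here was not tested, except that a filter removes genes and a left-out array removes samples.

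For genes called between the tumor groups (158, 96 of them at least 2-fold), centring on the median gave 306 (155 shared) and 159, a second quantile normalization 102 (87 shared), and array weights 3328 (all 158 shared) and 815. Fitting the tumors alone left 1 and 1, and an ordinary linear model 0 and 0, where limma had 3897 genes with an unadjusted p under 0.05. Without control tumors 1 and 2 the counts were 4886 (all 158 shared) and 1357, without 3, 4 and 5 the count was 82 (27 shared), and without 3 and 4 both were 6. Leaving out single arrays gave 16 to 1482 genes, and 15 to 543 at least 2-fold. Dnmt3a differed by -1.25 with the tumors alone (limma adjusted p = 0.105) and in the ordinary model (adjusted p = 0.110), and by -1.47 without control tumors 3 and 4 (adjusted p = 0.0768). Over all alternatives its adjusted p was 0.00397 to 0.121, and with single arrays left out the difference was -1.37 to -1.02.

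Camera with an estimated correlation called 4, 1 and 1 list shifts in control tumors against normal thymocytes, deficient tumors against normal thymocytes and between the tumor groups, in place of 15, 15 and 6. Fry called 17, 18 and 3: Polycomb (fry adjusted p = 0.0290) and germline genes (8.2e-04) gained a call in control tumors and DNA methylation machinery (0.0102), BCL2 family (1.2e-05) and interferon genes (0.00832) in deficient tumors against normal thymocytes. Between the tumor groups mitosis (fry adjusted p = 0.0545), mature T cell (0.344) and receptor signaling genes (0.335) lost theirs. Without control tumors 1 and 2 the number was 2, as DNA replication (camera adjusted p = 0.200), mature T cell (0.0528), receptor signaling (0.200) and germline genes (0.0958) lost theirs, and array weights ended that of receptor signaling (0.0554). With the dimmest 30% of genes removed 13, 11 and 5 list shifts were called in the 3 comparisons. The calls lost were oxidative phosphorylation and cholesterol synthesis in control tumors (camera adjusted p = 0.0858 for both), and Polycomb (0.147), germline genes (0.108), glycolysis (0.0578), ATF4 targets (0.0611), oxidative phosphorylation and cholesterol synthesis (0.154 for both) in deficient tumors, against normal thymocytes. Interferon (0.0407) and BCL2 family genes (0.0487) gained a call in the latter, and germline genes lost it between the tumor groups (0.163). With the replicate block 13, 12 and 7 were called: BCL2 family (0.0542) and cholesterol synthesis (0.0566) lost their call in control tumors, Polycomb (0.0552), oxidative phosphorylation (0.101) and cholesterol synthesis (0.121) in deficient tumors, and double-positive stage genes gained it between the tumor groups (0.0187). Marker lists, called 0, 0 and 1 times, were called 4, 3 and 0 times by fry and 0 times between the tumor groups with an estimated correlation. Between the tumor groups centring gave 2, and single arrays left out gave 1 to 2. In control tumors against normal thymocytes single arrays left out gave 0 to 2, and 2 and 1 were called without control tumors 3, 4 and 5 and without 3 and 4. The median SD with the dimmest 30% of genes removed was 0.174 in normal thymocytes, 0.312 in control tumors and 0.194 in deficient tumors, and with single arrays left out 0.143 to 0.157, 0.262 to 0.279 and 0.166 to 0.182. The correlation of both tumor groups' changes was 0.841 to 0.907 with single arrays left out.

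The replicate block, which treats samples with the same number as related, gave 0 called genes between the tumor groups and 0 of at least 2-fold with limma (3897 had an unadjusted p under 0.05 without the block), and a Dnmt3a difference of -1.02 (adjusted p = 0.121). It called 2 marker lists in each of the 3 comparisons. It turned Dnmt3b in control tumors against normal thymocytes (-0.17), Cd8a (-0.25) and macrophage markers (-0.17) between the tumor groups, and B cell (0.030), fibroblast and endothelium (0.0061) and adipocyte markers (-0.085) in deficient tumors against normal thymocytes. Whether the numbers pair the samples is not known. Same-numbered deficient and control tumors had correlations of their deviations of 0.338, -0.134, -0.0378 and -0.126. The first was the highest of any deficient with any control tumor, and not every sample correlated best with its own number.

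The turned results follow, each list with its median, while the direction is that of the test. Under cyclic loess, early thymocyte genes (0.0035), glycolysis (-0.0054), oxidative phosphorylation (-0.068), cholesterol synthesis (-0.091), ATF4 targets (0.012) and dendritic cell (-0.066) and fibroblast and endothelium markers (0.079) turned between the tumor groups. The same normalization turned imprinted genes (-0.016), oxidative phosphorylation (-0.038) and B cell (0.19), fibroblast and endothelium (0.12) and adipocyte markers (0.083) in deficient tumors against normal thymocytes, and Dnmt1 (-0.069) and oxidative phosphorylation (-0.073) in control tumors against normal thymocytes. A second quantile normalization turned early thymocyte genes (-0.032), glycolysis (0.00037), oxidative phosphorylation (-0.064), cholesterol synthesis (-0.099) and dendritic cell (-0.081) and fibroblast and endothelium markers (0.069) between the tumor groups. It also turned imprinted genes (-0.11) and B cell (0.10), fibroblast and endothelium (0.11) and adipocyte markers (0.014) in deficient tumors, and Dnmt3b (-0.026) in control tumors, against normal thymocytes. Centring turned cholesterol synthesis (0.12) and macrophage markers (0.071), and fry early thymocyte genes (0.050) and fibroblast and endothelium markers (0.0081), all between the tumor groups. Array weights turned early thymocyte genes (0.089), MHC genes (-0.031) and fibroblast and endothelium markers (0.014) between the tumor groups and p53 targets (0.026) in control tumors against normal thymocytes. With the dimmest 30% of genes removed, Notch targets (-0.092), glycolysis (0.085), cholesterol synthesis (0.077), ATF4 targets (0.042) and NK cell markers (0.11) turned between the tumor groups, imprinted genes (0.10) in deficient tumors and p53 targets (0.15) and neutrophil markers (-0.11) in control tumors against normal thymocytes.

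Without control tumors 1 and 2, MYC targets (-0.0066), early thymocyte genes (0.16), double-positive stage genes (0.23), p53 targets (0.28), MHC genes (-0.11), oxidative phosphorylation (-0.0083), cholesterol synthesis (0.12), ATF4 targets (0.029) and NK cell (0.20) and fibroblast and endothelium markers (0.16) turned between the tumor groups, and p53 targets (-0.029) and imprinted genes (-0.17) in control tumors against normal thymocytes. Without control tumors 3, 4 and 5, Myc (0.29), Mycn (0.069), Cd3e (-0.095), Cd8a (-0.60), DNA methylation machinery (-0.048), Notch targets (-0.0024) and macrophage (-0.11) and erythroid markers (-0.011) turned between the tumor groups. In control tumors against normal thymocytes the same fit turned Dnmt3b (-0.30), fibroblast and endothelium (0.035) and neutrophil markers (-0.47), the last called with a limma adjusted p = 0.0360. Without control tumors 3 and 4, Myc (0.12), glycolysis (0.055) and B cell (-0.062) and dendritic cell markers (0.010) turned between the tumor groups, and Dnmt3b (-0.049), fibroblast and endothelium (-0.027) and neutrophil markers (-0.54, limma adjusted p = 0.00426, with 0.00426 to 0.985 over all alternatives) in control tumors against normal thymocytes.

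Leaving out single arrays turned some results, given as the range of their medians or differences. Between the tumor groups these were Cd8a (-0.25 to 1.12), early thymocyte genes (-0.077 to 0.12), double-positive stage genes (-0.27 to 0.21), Notch targets (-0.12 to 0.057), p53 targets (-0.055 to 0.10), MHC genes (-0.051 to 0.15), glycolysis (0.055 to 0.12), oxidative phosphorylation (-4.6e-05 to 0.11), cholesterol synthesis (-0.033 to 0.17), ATF4 targets (-0.051 to 0.10) and macrophage (-0.17 to 0.17), dendritic cell (-0.17 to -0.070) and fibroblast and endothelium markers (-0.025 to 0.072). In deficient tumors against normal thymocytes they were p53 targets (-0.18 to 0.0024) and B cell (-0.13 to 0.030) and fibroblast and endothelium markers (-0.090 to 0.034). In control tumors against normal thymocytes they were Dnmt3b (-0.073 to 0.19), p53 targets (-0.022 to 0.20), imprinted genes (-0.15 to 0.027) and neutrophil markers (-0.17 to 0.26).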

Other observations

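The gene families and the neighbor test below were chosen after the data were seen. Families were matched by gene symbol, without kinases, binding proteins, regulators and pseudogenes that share a symbol's beginning.

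Members of further families, a few of them also in the fixed lists, were called between tumors and normal thymocytes, while the families themselves were not tested there. Nucleoporins, the proteins of the nuclear pore, were higher in control tumors for 13 of 20 members and in deficient tumors for 16, with medians of log2 0.82 and 1.14 and none lower. Of 60 cytosolic ribosomal proteins 21 were higher and none lower in control tumors and 28 higher and 1 lower in deficient tumors, with medians of 0.32 and 0.31, which fell to 0.13 and 0.070 after cyclic loess. Mitochondrial ribosomal proteins were higher for 19 of 77 members (none lower, median 0.27, but 0.087 after a second quantile normalization) and for 39 (7 lower, median 0.55, but 0.26 after the same). Translation initiation factors were higher for 22 of 41 members (2 lower, median 0.54, but 0.32 after cyclic loess) and for 24 (5 lower, median 0.67). Core and linker histones were lower for 18 of 42 members in each tumor group, with medians of -0.56 and -0.39 and none higher. The GTPases of the GIMAP family, which act in lymphocyte survival, were lower for 2 of 8 members in control tumors and for 5 in deficient tumors, with medians of -0.44 and -1.48. Among 340 zinc finger genes 83 were higher and 30 lower, and 125 higher and 47 lower, with medians of 0.14 (0.22 after cyclic loess) and 0.28. All these medians kept their sign after a second quantile normalization, centring and cyclic loess.

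Between the tumor groups, nucleoporins had a median of 0.38 (exact two-sided permutation p of their mean 0.0159) and mitochondrial ribosomal proteins 0.24 with 2 called (exact two-sided permutation p = 0.0159), and both stayed positive under all scalings run, though they fell to 0.25 and 0.072 after a second quantile normalization and to 0.25 and 0.10 after cyclic loess. Histones had a median of 0.13 with 1 called (exact two-sided permutation p = 0.0476), which fell to 0.069 after a second quantile normalization, and zinc finger genes 0.14 with 1 lower (exact two-sided permutation p = 0.119), 0.086 after the same normalization. Cytosolic ribosomal proteins had a median of -0.05 (exact two-sided permutation p = 0.349; -0.084 after a second quantile normalization and -0.0099 after centring) and GIMAP genes -1.05 (exact two-sided permutation p = 0.0794), with no member called. The median of initiation factors was 0.01 (exact two-sided permutation p = 0.611) and turned to -0.058 after cyclic loess and to -0.034 after a second quantile normalization. These p-values are not adjusted for the 8 families examined.

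Genes called between the tumor groups lay next to one another more often than random genes. A called gene of the same direction was found among the 3 nearest tested genes on either side for 17 of 158, against a median of 4 and a 95th percentile of 10 in random sets matched on mean level (permutation p = 8e-04). This p treats genes as independent, though all were measured on the same tumors, and does not measure the spread between tumors. An earlier version of the test, with sets not matched on level, was also run. The neighbors included Ifi203 with Ifi207, Rsad2 with Cmpk2 and Snora73a with Snora73b, so shared regulation of related genes may account for part of the 17. The others were Fstl3, Prss57 and Palm, Trim25 with Dgke, Fam217a with Eci2, Gadd45gip1 with Syce2, and Tmie with Als2cl. A regional change along the chromosome is a hypothesis that this count meets, and the share of it that comes from related genes lying together was not tested.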
